A study of Mus musculus with 4 samples.

How the data were processed

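Ovarian leukocytes of female C57BL/6J mice aged 10 to 12 weeks were compared 48 h after gonadotropin treatment or saline, with 5 mice per group. Per the labels' protocols, ovaries were dissociated, viable CD45+ cells were sorted, the cells of each mouse were stained with their own TotalSeq-B hashtag antibody, and the 5 mice of a group were pooled and run as 1 10x Genomics Chromium 3' v3 library sequenced on an Illumina HiSeq 2500. The treatment is therefore confounded with the pool, its staining and its library, which no model here can separate.

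The values used are the deposited counts, whole numbers of UMIs per gene and barcode, which the authors left without normalization. The submitters' processing notes name bcl2fastq, Cell Ranger, Seurat and the genome build mm10, without versions. The deposited table holds 6468 barcodes and 32285 genes, both libraries together, and keeps barcodes that the hashtags call doublets or negative. Its lowest barcode total is 501 UMIs, so barcodes near and below 500 had been left out before. The hashtag calls are those deposited by the authors, and their threshold is not stated. The deposited hashtag margin is a score, the difference between the best and the next normalized hashtag value of a barcode per the file headers, and was not used. Sums per barcode were checked against the deposited totals and were equal. The files give gene symbols only, made unique with a numeric suffix. Positions are those of GRCm38.p6 and were matched by symbol.

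Barcodes called as 1 hashtag, with at least 500 genes and under 10% mitochondrial UMIs, were kept. This left 4918 of 5031 single-hashtag barcodes and took out 68 gonadotropin and 45 untreated ones. The 693 and 655 hashtag doublets and 69 and 20 negative barcodes of the gonadotropin and untreated pools were left out. The deposited mouse column gives the mouse of the first hashtag for 340 of the 1348 doublets, and in all 1348 it is the lower numbered mouse of the tag pair plus 1. Summed UMIs per mouse ran from 2608262 to 7097779 in the gonadotropin and from 2559097 to 6500466 in the untreated group. Intervals and floors cover counting error only, at 95% (Clopper-Pearson), and a count of 0 is given the upper limit of 3 counts. As a check only, scrublet called 107 barcodes doublets, of which 11 were among the kept cells.

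Cells of both groups were clustered together with scanpy 1.11.5, without batch correction, since it would have removed the treatment with the pool. Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components and 15 neighbors went into Leiden clustering by igraph 0.11.9 at a resolution of 0.2. Clusters 1, 5, 6, 7 and 9 were divided again with 1000 genes and 15 components at 0.5. The files hold no annotation of cell types, so clusters were named from fixed marker sets of 29 cell types, and clusters of the same name were joined. Names end in "like" because they rest on transcripts. Erythrocyte-like cells were kept in the share denominators.

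The mouse was the replicate. Shares of cell types, and shares of cycling cells after thinning each cell to 2000 UMIs, were compared by exact two-sided permutation over all assignments of 5 against 5 mice, with Benjamini-Hochberg adjustment. For changed genes, counts were summed per mouse over all cells, or over the cells of 1 type in mice with at least 20 of them, and tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) at an adjusted p of 0.05. B cell-like clusters 0 and 2, CD4 T cell-like, CD8 T cell-like and NK cell-like cells had enough such mice. CPM use TMM-scaled library sizes, except that values of a single cluster of a class and the per-mouse Hbb-bs values of B cells use plain UMI totals. Differences in the change between types were tested as an interaction of type and treatment in edgeR, with the mouse as a term. Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, for lists with at least 3 measured members, and again with an estimated correlation. The 40 lists covered 28 programmes, 3 signs of cell quality and 9 other cell types of the ovary or blood.

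Comparisons, tests, lists, marker sets and most alternative settings were written down before the data were examined. So was the rule for named genes. For all CD45+ cells and the 3 types with the most cells it takes the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean log2 CPM of at least 5 and no overlap between the mice of the groups. For the other types it takes 3 and 3. Gene models named Gm or ending in Rik, mitochondrial and ribosomal protein genes, immunoglobulin and T cell receptor segments and Xist stand outside the rule, and members of the lists and markers may be named too. The mouse numbers are only names, and no pairing across the groups was assumed.

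The procedure was tested on simulated data with 200 changed genes at the depths and replicate numbers of these data. At a fold of 2, edgeR recovered 86.6% of changed genes in all CD45+ cells, 91.0% in B cell-like cluster 0, 80.6% in CD4 T cell-like, 70.1% in B cell-like cluster 2, 83.6% in NK cell-like and 80.6% in CD8 T cell-like cells. At a fold of 1.5 the recovery was 28.4% to 59.7%. In all CD45+ cells 14 of 193 calls were not simulated as changed.

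The alternative settings fixed at that stage were a log scale for shares, leaving out the 5% of cells with the most and the fewest UMIs, leaving the most changed type out of the denominator, another clustering resolution, library size in place of TMM, DESeq2 1.42.0, limma-voom, no filter on low counts, equal cell numbers per type and mouse, thinned counts, at least 50 cells per mouse, leaving out genes that free RNA could carry, the mouse number as a block, fry, an estimated correlation, and each mouse left out. Added after the data were seen were hashtag doublets counted by their first tag and, for shares, by their other tag or the deposited mouse column, cells near hashtag doublets left out, erythrocyte-like cells left out, stress genes left out of the counts, the largest cluster of a class alone, thinned counts per type and 4 further types with fewer cells per mouse. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9, and R 4.3.3.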

Results

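Leukocytes of the mouse ovary were profiled by droplet single-cell RNA sequencing 48 h after gonadotropin treatment, with saline-treated mice as the untreated group. Gonadotropins are the hormones that drive follicle growth and ovulation, and CD45 is the surface protein carried by leukocytes. Cells sorted for CD45 came from 5 gonadotropin mice and 5 untreated mice, each mouse tagged with its own hashtag antibody and pooled with the other mice of its group. The gonadotropin pool gave 3253 barcodes and the untreated pool 3215, and 4918 cells assigned to 1 mouse passed the filters, 2423 and 2495 of them. A mouse contributed 290 to 828 cells in the gonadotropin group and 296 to 726 in the untreated group, and the summed counts per mouse ranged from 2559097 to 7097779 UMIs. The median cell held 7034 UMIs and 2568 genes in the gonadotropin group and 7664 UMIs and 2654 genes in the untreated group. The mouse is the replicate throughout. All mice of a group shared 1 library, so a library effect and the treatment cannot be told apart, and the spread between mice does not include the spread between libraries.

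Clustering divided the ovarian leukocytes into 20 groups of cells, 18 of which were named by fixed marker genes. B cells made up 3 of them. B cell-like cluster 0, with 1834 cells, was led by Fcer2a, Ighd, Cr2 and Ebf1, genes known from mature follicular and marginal zone B cells. B cell-like cluster 2, with 553 cells, was led by Agbl1, Sox5, Fcrl5 and Zbtb32, with Il5ra, Mzb1 and Bhlhe41 among the next genes, of which Il5ra, Zbtb32 and Bhlhe41 are known from B-1 cells. Its median cell held 13907 UMIs against 5940.5 in cluster 0. T cells were mainly CD4 T cell-like (593 cells) and CD8 T cell-like (481 cells), natural killer (NK) cell-like cells numbered 506, and macrophage-like cells 216. The remaining groups held 19 to 111 cells each.

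The first comparison asked whether the makeup of the ovarian leukocytes differed after gonadotropin. B cells formed a smaller part of the leukocytes of gonadotropin mice, at 42.0% ± 2.97 (SD, n = 5) of a mouse's cells against 54.5% ± 4.54 (SD, n = 5), with no overlap between the mice. The gap lay mostly in B cell-like cluster 2, which made up 6.58% ± 2.70 of the cells of gonadotropin mice and 16.9% ± 4.17 of those of untreated mice, again without overlap. Of all barcodes placed in cluster 2, 53.8% in the gonadotropin and 41.9% in the untreated pool were hashtag doublets and had been left out, against 10.0% and 13.5% in cluster 0. Cluster 0 made up 34.7% ± 5.12 and 36.9% ± 6.49 (SD, n = 5 each). NK cell-like cells had a mean share of 13.8% ± 4.48 in gonadotropin and 6.69% ± 1.75 in untreated mice. Macrophage-like cells had 6.76% ± 2.56 and 3.11% ± 1.35, and neutrophil-like cells 3.01% ± 0.87 and 1.42% ± 0.73 (SD, n = 5 each). Erythrocyte-like cells, led by hemoglobin genes, numbered 21 and were found in 4 of the 5 gonadotropin mice, at a mean share of 0.83% ± 0.54 (SD, n = 5). No such cell was among the 2495 untreated cells, which allows a share of up to 0.120%. CD4 T cell-like cells stood at 11.5% ± 1.49 and 13.2% ± 5.74, and CD8 T cell-like cells at 9.38% ± 1.52 and 9.92% ± 1.2 (SD, n = 5 each).

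In exact two-sided permutation tests over all assignments of the mice, both the B cell total and B cell-like cluster 2 reached the smallest p the design allows (p = 0.0079), and NK cell-like, macrophage-like and neutrophil-like cells each gave p = 0.032. The erythrocyte-like share gave an exact permutation p of 0.048. After Benjamini-Hochberg adjustment over 21 types and classes none of the shares passed 0.05. The smallest adjusted p in these permutation tests was 0.083, for both B cell shares. A type at the smallest p could not pass alone. It would pass if 4 types reached that p, or if more types came close to it. At another clustering resolution, with fewer groups to adjust for, both B cell shares passed (exact permutation test, adjusted p = 0.048). When hashtag doublets were counted by their first tag, B cells in all, B cell-like cluster 2 (a difference of −12.4 percentage points), macrophage-like and neutrophil-like cells passed. These calls rest on the choice of tag. With the doublets given to their other tag the difference of B cell-like cluster 2 was −11.4 (exact permutation test, adjusted p = 0.222), by the deposited mouse column it was −11.7 (exact permutation test, adjusted p = 0.111), and no share passed either way. With cells near hashtag doublets left out the difference of B cell-like cluster 2 was −8.17 and did not pass.

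**Figure D1:**
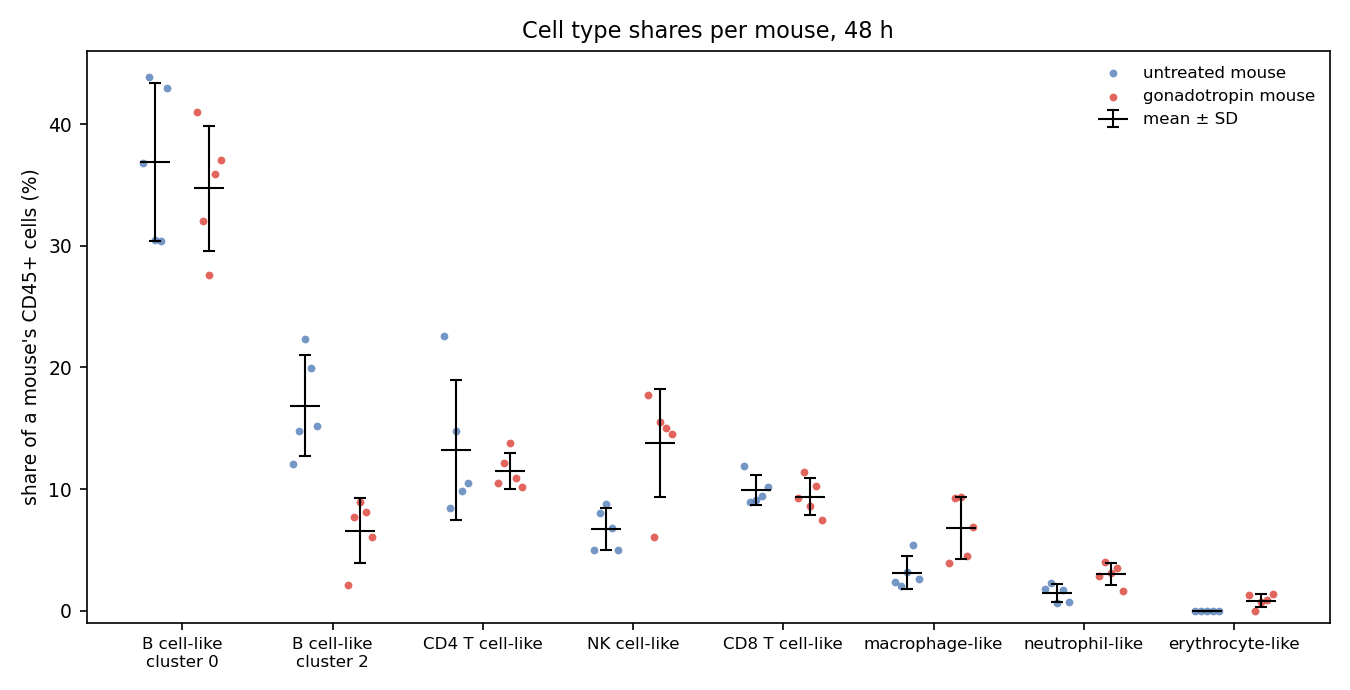
Share of each mouse's CD45+ cells (%, vertical axis) in 8 cell types (horizontal axis), with 1 point per mouse, untreated in blue and gonadotropin in red, and mean ± SD as black bars. The gonadotropin mice lie below every untreated mouse in B cell-like cluster 2, with means of 6.58% and 16.9%.

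The second comparison took all CD45+ cells of a mouse together, so that it reads the cell mix as well as the expression within cells. Of 11266 genes tested, 560 were higher and 467 lower in gonadotropin mice (edgeR quasi-likelihood test, adjusted p under 0.05, n = 5 each). Hemoglobin transcripts stood furthest apart, with Hbb-bs at 6647 ± 4043 CPM (SD) in gonadotropin and 2.52 ± 1.08 CPM in untreated mice. Hba-a1 stood at 1998 ± 1264 and 0.69 ± 0.45 CPM, Hba-a2 at 1578 ± 1017 and 0.42 ± 0.35 CPM and Hbb-bt at 1735 ± 1129 and 1.18 ± 0.90 CPM. These 4 genes belong to the list of erythrocyte genes among the lists of other cells, and the kept erythrocyte-like cells above were all of gonadotropin mice. Of the hashtag doublets left out, 3 in the gonadotropin and 2 in the untreated pool were placed with them. Among leukocyte genes, Il18rap, a subunit of the interleukin-18 receptor, rose by 1.32 ± 0.18 (log2 fold change ± SE; edgeR adjusted p = 0.00166) to 93.4 CPM from 37.8 CPM. The transcription factor Tbx21, which drives NK and type 1 T cell programmes, rose by 1.09 ± 0.19 (edgeR adjusted p = 0.00539). Csf3r, the granulocyte colony-stimulating factor receptor (1.28 ± 0.19), Hp, which encodes haptoglobin (1.25 ± 0.24), Lrmda (1.22 ± 0.17) and Itgam, the integrin CD11b of myeloid and NK cells (1.05 ± 0.25), were higher as well (edgeR adjusted p at most 0.0192).

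The rule for named genes asks for a minimum of expression and no overlap between the mice. Among the genes it took, Ctla4, an inhibitory receptor of lymphocytes on chromosome 1 (60909025 to 60915832, GRCm38.p6), fell furthest, at −1.25 ± 0.24 (edgeR adjusted p = 0.00852), from 57.6 to 24.2 CPM. Il5ra (−1.12 ± 0.12), Mzb1 (−0.92 ± 0.11), Agbl1 (−0.91 ± 0.11) and Nid1 (−0.89 ± 0.20) fell too, and all 4 are among the genes that mark B cell-like cluster 2, whose share was lower. Myc, a growth-promoting transcription factor, fell by 0.90 ± 0.10 (SE; edgeR adjusted p = 0.0005), from 46.7 to 24.8 CPM. Phgdh, the first enzyme of serine synthesis, changed by −0.82 ± 0.14, Lmna, which encodes lamin A, by −0.97 ± 0.22, Pafah1b3 by −0.89 ± 0.13 and Hepacam2 by −0.80 ± 0.18 (edgeR adjusted p at most 0.0172). With the same number of cells of each type drawn from every mouse, 49 genes passed, 41 of them shared with the 1027 above. The draw was made once and left out types absent from any mouse. It took the number of the mouse with the fewest, such as 80 cells of B cell-like cluster 0, 20 NK cell-like cells and 12 of B cell-like cluster 2. Calls lost in this draw, here and below, therefore mix fewer cells and lower power with the even cell mix. Il18rap (0.66), Tbx21 (0.74) and Hbb-bs (3.02) stayed higher in that draw, while Agbl1 (0.15), Il5ra (−0.11) and Mzb1 (−0.17) did not pass. Nor did Csf3r (0.23), Hp (0.34), Lrmda (0.29), Itgam (0.23), Ctla4 (−0.46), Lmna (−0.44), Myc (−0.62), Nid1 (−0.19), Pafah1b3 (−0.28), Phgdh (−0.36) and Hepacam2 (−0.11). The count of 1027 was 682 without gonadotropin mouse 4.

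Of 37 gene lists with at least 3 measured members, 11 stood apart from the other genes in all CD45+ cells. In the cytotoxicity list all 16 measured genes had a positive log2 fold change, and 12 were higher over all genes tested and 15 adjusted over the list alone (camera adjusted p = 5.88e-11; adjusted p = 0.309 with an estimated correlation). Among them were the pore-forming protein Prf1 (1.03 ± 0.28), the protease Gzmb (1.18 ± 0.31), the activating receptor Klrk1 (0.74 ± 0.18) and the chemokine Ccl5 (0.94 ± 0.21). Phagocytosis and efferocytosis receptors were positive in 18 of 18 genes, with 6 higher over all genes and 7 adjusted over the list alone (adjusted p = 0.309 with an estimated correlation), such as Mertk (2.19 ± 0.52), a receptor for apoptotic cells, and the scavenger receptor Stab1 (1.35 ± 0.37). Genes of lipid uptake and lipid-laden macrophages were positive in 18 of 19, with 4 higher by both counts, including Trem2 (1.43 ± 0.29) and the lysosomal protease Ctsd (0.74 ± 0.13) (adjusted p = 0.414 with an estimated correlation). Complement genes were positive in 10 of 11, with 3 higher over all genes and 7 adjusted over the list alone, C3 (1.12 ± 0.30) and the receptor C5ar1 (1.01 ± 0.27) among them (adjusted p = 0.414 with an estimated correlation).

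S100 alarmins and neutrophil granule genes were positive in 10 of 13, with 3 higher over all genes and 6 adjusted over the list alone, among them S100a9 (1.23 ± 0.30) and Mmp9 (1.67 ± 0.37) (adjusted p = 0.372 with an estimated correlation). The prostaglandin and leukotriene list was positive in 11 of 15, with Alox5ap (0.84 ± 0.22) higher over all genes and 7 genes adjusted over the list alone (adjusted p = 0.414 with an estimated correlation). These myeloid and cytotoxic lists moved with the mean shares of macrophage-like, neutrophil-like and NK cell-like cells. The type I interferon response was positive in 18 of 20 genes, and Oasl2 (0.89 ± 0.17), Ifih1 (0.72 ± 0.20) and Rtp4 (0.63 ± 0.15) were higher by both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.000371; adjusted p = 0.46 with an estimated correlation). With the same number of cells of each type drawn from every mouse, cytotoxicity genes were positive in 11 of 15 (limma camera adjusted p = 0.184) and type I interferon genes in 13 of 19 (limma camera adjusted p = 0.271). Phagocytosis receptors were positive in 8 of 15 there, lipid uptake genes in 9 of 18, complement genes in 3 of 10, S100 genes in 4 of 9 and the prostaglandin and leukotriene list in 7 of 13. All 5 pointed down against the other genes and none was called (limma camera adjusted p at least 0.271). Inflammatory and NF-kB genes (4 of 14 positive, limma camera adjusted p = 0.000293), matrix remodelling genes (2 of 6, 0.0073) and cholesterol synthesis genes (6 of 17, 0.0138) were called as lower in that draw only. With all cells the first 2 pointed up and none of the 3 was called (limma camera adjusted p = 0.485, 0.0885 and 0.187). In that draw Klrk1 (−0.073), Prf1 (−0.0049) and C5ar1 (−0.31) changed direction and none of the 3 passed. The erythrocyte list, with 4 of 4 higher by both counts, had an adjusted p = 0.178 with an estimated correlation.

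Lists that read cell quality moved too. All 25 ribosomal protein genes had a negative log2 fold change, 21 lower over all genes and 23 adjusted over the list alone (adjusted p = 0.379 with an estimated correlation), and so had all 13 mitochondrially encoded genes, 12 of them lower over all genes and 13 adjusted over the list alone (adjusted p = 0.178 with an estimated correlation). With equal cell numbers per type 3 of 25 ribosomal protein genes and 2 of 13 mitochondrially encoded genes were positive and both lists were still called (limma camera adjusted p at most 4.39e-07), but most falls shrank. Of the 21 and 12 genes lower above, 3 and 2 passed in that draw, with Rpl7 going from −0.25 to −0.04, Rps18 from −0.35 to −0.10, mt-Co1 from −0.30 to −0.11 and mt-Co3 from −0.21 to 0.02. The median mitochondrial share per mouse was 1.80% to 1.96% in gonadotropin and 2.21% to 2.34% in untreated mice. The stress list had 8 genes lower and 2 higher over all genes, and 10 and 3 adjusted over the list alone (adjusted p = 0.379 with an estimated correlation). Lists of other ovarian cells gave no call in limma camera tests: granulosa cell genes (3 measured, adjusted p = 0.635, with Kctd14 at −0.96 ± 0.20), luteal and theca genes (6 measured, 0.485, with Mgst1 at 0.76 ± 0.22, or −0.15 with equal cell numbers per type), cumulus genes (3 measured, 0.453), endothelial genes (4 measured, 0.87) and surface epithelium genes (3 measured, 0.15).

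The third set of comparisons looked within cell types, summing the cells of 1 type per mouse. In B cell-like cluster 0, 54 genes were higher and 50 lower of 8275 tested (edgeR, adjusted p under 0.05, n = 5 each). Fos, a subunit of the AP-1 transcription factor on chromosome 12 (85473890 to 85477274, GRCm38.p6), fell by 1.36 ± 0.12 (log2 fold change ± SE; edgeR adjusted p = 1.88e-08), from 283 ± 61.4 to 114 ± 19.8 CPM (SD, n = 5 each). Junb, another AP-1 subunit, changed by −1.01 ± 0.09 (edgeR adjusted p = 2.01e-08), from 325 to 161 CPM. Plaur, the urokinase receptor, changed by −1.12 ± 0.14, the atypical NF-kB regulator Nfkbid by −0.87 ± 0.11, the insulin receptor substrate Irs2 by −0.93 ± 0.18 and the kinase Sik1 by −0.66 ± 0.11. The histone demethylase Kdm6b (−0.63 ± 0.16), Txlna (−0.69 ± 0.15), Rsl24d1 (−0.54 ± 0.14) and Yeats4 (−0.52 ± 0.10) were lower as well (edgeR adjusted p at most 0.0381).

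Among the genes that the rule took, Fgf13 rose most, at 1.13 ± 0.16 (edgeR adjusted p = 0.000122), from 40.9 to 84.1 CPM. Stat4, a transducer of cytokine signals, rose by 0.60 ± 0.10 from 234 to 349 CPM. The zinc transporter Tmem163 rose by 0.45 ± 0.08, Bcar3 by 0.57 ± 0.09, the small GTPase Rab21 by 0.52 ± 0.09, Rapgef2 by 0.49 ± 0.12 and the deacetylase Hdac7 by 0.44 ± 0.11 (edgeR adjusted p at most 0.041). Rai1 (0.78 ± 0.17), the phosphatase Ppm1e (0.62 ± 0.16) and Mlxip (0.45 ± 0.10) rose too. Transcripts that B cells are not known to make were also higher in this type. Hbb-bs stood at 30.2 ± 6.28 CPM in gonadotropin and 2.72 ± 1.93 CPM in untreated B cells (adjusted p = 1.47e-08), and Lyz2, the lysozyme of myeloid cells, at 34.8 ± 3.60 and 12.5 ± 2.94 CPM (adjusted p = 2.79e-05; edgeR, SD, n = 5 each).

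**Figure D2:**
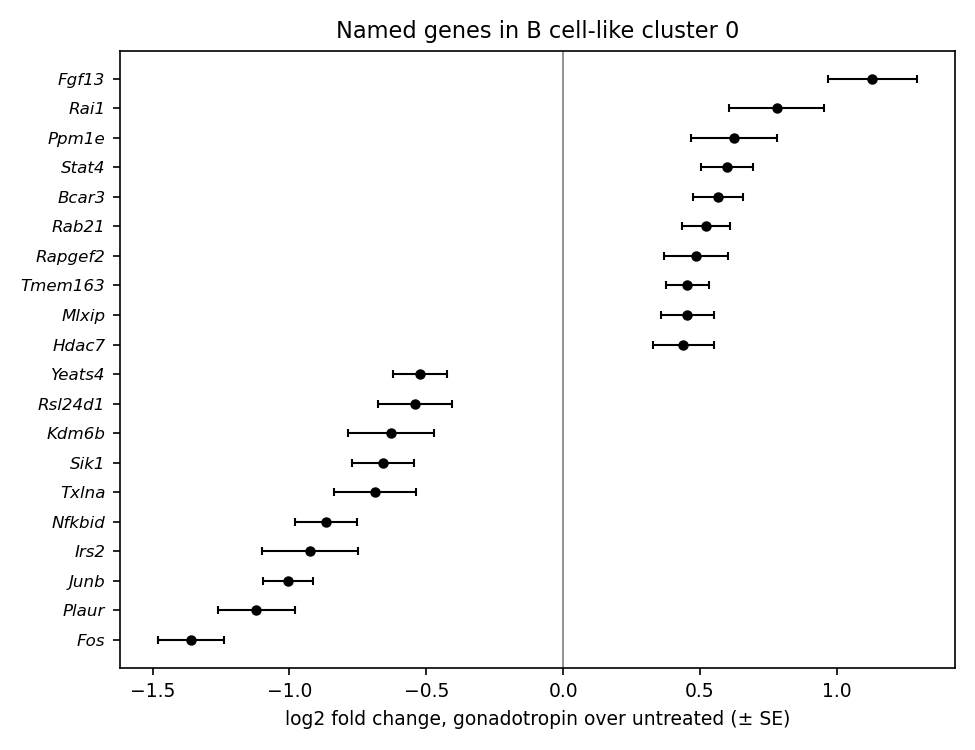
Log2 fold change of gonadotropin over untreated mice (horizontal axis, points, with SE as bars) for the 20 named genes (vertical axis) in B cell-like cluster 0, n = 5 mice per group. The values run from −1.36 for Fos to 1.13 for Fgf13.

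Of 25 lists tested in B cell-like cluster 0, 8 stood apart. Cholesterol synthesis genes were negative in 14 of 14, with Cyp51 (−1.10 ± 0.21) lower over all genes and 3 lower adjusted over the list alone (camera adjusted p = 0.00219; adjusted p = 0.453 with an estimated correlation). T cell activation genes were positive in 1 of 7, with Nr4a1, an immediate early nuclear receptor, at −1.05 ± 0.24 and 3 lower adjusted over the list alone (adjusted p = 0.126 with an estimated correlation). Oxidative phosphorylation genes were positive in 2 of 22, with 0 lower over all genes and 2 adjusted over the list alone, and glycolysis genes in 2 of 14, with 0 lower over all genes and 3 adjusted over the list alone (adjusted p = 0.453 with an estimated correlation for each). MHC class II genes were positive in 11 of 12, with 0 higher over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0466; adjusted p = 0.542 with an estimated correlation). Ribosomal protein genes were positive in 2 of 25, with 4 lower over all genes and 7 adjusted over the list alone (adjusted p = 0.461 with an estimated correlation), and mitochondrially encoded genes in 0 of 13, with 4 lower over all genes and 7 adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). The stress list had 4 lower and 2 higher over all genes, and 8 and 6 adjusted over the list alone (adjusted p = 0.453 with an estimated correlation). The count of 104 genes in B cell-like cluster 0 was 37, 50, 54 and 50 without gonadotropin mouse 4 or 5 or untreated mouse 2 or 5, and 68 without untreated mouse 3. It was 242 without gonadotropin mouse 2 and 227 without untreated mouse 4, and the 8 lists were 5 without gonadotropin mouse 1.

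In B cell-like cluster 2, the UMI-rich B cells whose share was lower, 14 genes were higher and 12 lower of 7445 tested, with 4 gonadotropin mice holding enough cells and 5 untreated mice. Ctla4 fell by 1.57 ± 0.23 (SE; edgeR adjusted p = 0.000737), from 123 ± 42.3 to 41.8 ± 7.1 CPM (SD, n = 5 and 4). The NF-kB subunit Rel changed by −0.65 ± 0.11, the transcription factor Klf4 by −1.25 ± 0.26 and Odc1, the first enzyme of polyamine synthesis, by −0.68 ± 0.14, beside Fos (−1.16 ± 0.13), Junb (−0.95 ± 0.15), Zfp36 (−1.02 ± 0.20), Ier2 (−0.91 ± 0.14) and Atf3 (−0.92 ± 0.20) of the stress list. Among the genes that rose were the phosphatase Ptprj (0.65 ± 0.09), the thiol reductase Ifi30 of antigen processing (0.60 ± 0.12), the RNA-binding protein Msi2 (0.55 ± 0.11), the transcription factor Bcl11a (0.53 ± 0.11), Sorcs2 (0.68 ± 0.15) and Fam49b (0.45 ± 0.10).

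Of 28 lists, 3 stood apart in this cluster. T cell activation genes were positive in 1 of 6, with Ctla4 and Nr4a1 (−2.19 ± 0.45) lower by both counts, over all genes and adjusted over the list alone (adjusted p = 0.104 with an estimated correlation). Of 3 phagocytosis receptors measured, Mrc1 (1.56 ± 0.35) and Cd300lf (1.06 ± 0.21) were higher by both counts (adjusted p = 0.104 with an estimated correlation). The stress list had 5 lower and 2 higher over all genes and 8 and 3 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). Of these 26 genes 1 passed when cells near hashtag doublets were left out and 5 when the cells with the highest and lowest UMI totals were left out, where 7 genes passed in all. Without gonadotropin mouse 2 or 4 the count was 9 or 11, and without untreated mouse 2, 4 or 5 it was 10, 11 or 8. The 3 lists were 5 without untreated mouse 2 or 3.

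In CD4 T cell-like cells 24 genes were higher and 24 lower of 5380 tested (edgeR, n = 5 each). The calcium-binding proteins S100a6 and S100a4 and the galectin Lgals1, genes high in activated and memory T cells, rose together. S100a6 rose by 1.56 ± 0.24 (SE; edgeR adjusted p = 0.000666), from 83.2 ± 50.8 to 255 ± 74.1 CPM (SD, n = 5 each). S100a4 rose by 2.03 ± 0.33 and Lgals1 by 1.14 ± 0.17. Tested directly, the change in CD4 T cell-like cells was more positive than that in B cell-like cluster 0 for S100a4 (2.64 ± 0.34), S100a6 (2.29 ± 0.30) and Lgals1 (1.56 ± 0.22). Ccl5 rose by 1.86 ± 0.44. Cluster 6.0, led by Rora, Itgb1 and Cd28, made up 27.6% ± 13.4 of the CD4 T cell-like cells of gonadotropin mice and 14.4% ± 4.04 of those of untreated mice (SD, n = 5 each; exact permutation p = 0.032, adjusted p = 0.083). In the other cluster alone, cluster 3, which had the naive T cell genes Lef1 and Tcf7 among its leading genes, S100a6 stood at 5.83 and 6.86 CPM, S100a4 at 4.23 and 2.31 CPM and Ccl5 at 2.72 and 4.25 CPM, and Lgals1 was at −0.29 ± 0.22 (edgeR adjusted p = 0.613).

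Several CD4 T cell-like genes stood apart in that single cluster as well as in all CD4 T cell-like cells. The kinase Prkce was at 0.73 ± 0.17 in all of them and 0.82 ± 0.18 in cluster 3, the deacetylase Hdac8 at 0.75 ± 0.15 and 0.81 ± 0.17, the cell cycle regulator Rb1 at 0.63 ± 0.14 and 0.69 ± 0.16, Fryl at 0.56 ± 0.12 and 0.64 ± 0.13 and Tex14 at 1.07 ± 0.21 and 0.99 ± 0.24 (edgeR adjusted p at most 0.0329). Atxn1 (0.80 ± 0.16) and Rab8b (0.64 ± 0.15) passed over all of them. In cluster 3 they stood at 0.21 ± 0.17 and 0.42 ± 0.19 and did not pass. Among the genes that fell, Junb changed by −0.90 ± 0.13 and −0.88 ± 0.13, the phosphatase Dusp10 by −0.67 ± 0.14 and −0.56 ± 0.13, the cyclic AMP phosphodiesterase Pde4d by −0.66 ± 0.16 and −0.66 ± 0.16, the noncoding RNA Gas5 by −0.48 ± 0.11 and −0.44 ± 0.10 and Nsa2 by −0.38 ± 0.09 and −0.42 ± 0.10. Pnrc1 (−0.47 ± 0.11), Srsf5 (−0.43 ± 0.10) and Ddx5 (−0.36 ± 0.09) passed over all of them. In cluster 3 they stood at −0.40 ± 0.12, −0.42 ± 0.11 and −0.28 ± 0.09 and did not pass.

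Of 21 lists in CD4 T cell-like cells 6 stood apart. S100 genes were positive in 4 of 4, with 2 higher over all genes and 4 adjusted over the list alone (camera adjusted p = 6.53e-09; adjusted p = 0.114 with an estimated correlation). Type I interferon genes were positive in 9 of 9, with 0 higher over all genes and 4 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Inflammatory and NF-kB genes were positive in 1 of 5, with 0 lower over all genes and 1 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Ribosomal protein genes were positive in 3 of 25, with 2 lower over all genes and 14 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation), mitochondrially encoded genes in 1 of 13, with 2 lower over all genes and 7 adjusted over the list alone (adjusted p = 0.302 with an estimated correlation), and the stress list had 3 lower and 2 higher, or 8 and 2 adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). The count of 48 genes fell to 7, 20, 8, 27, 10 and 31 without gonadotropin mouse 4 or 5 or untreated mouse 1, 2, 3 or 5, and rose to 76 without gonadotropin mouse 2. With at least 50 cells per mouse 21 passed, 13 of them shared.

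In CD8 T cell-like cells 61 genes were higher and 33 lower of 5609 tested (edgeR, n = 5 each). Klre1, a receptor of the killer lectin-like family on chromosome 6 (129559365 to 129585828, GRCm38.p6), rose by 1.70 ± 0.24 (SE; edgeR adjusted p = 3.75e-05), from 24.1 ± 11.2 to 85.8 ± 14.4 CPM (SD, n = 5 each). The cytotoxicity list was positive in 10 of 10 measured genes, with 5 higher over all genes and 6 adjusted over the list alone (camera adjusted p = 6.85e-10; adjusted p = 0.0574 with an estimated correlation). These were the protease Gzma (2.57 ± 0.59), the transcription factors Eomes (1.43 ± 0.31) and Tbx21 (1.09 ± 0.26), the activating receptor Klrk1 (0.95 ± 0.24) and Ccl5 (0.73 ± 0.15). Of the chemokine list, Xcl1 (1.36 ± 0.34) and Ccl5 were higher by both counts among 3 measured genes, and the list was called with an estimated correlation too (adjusted p = 0.0395 with an estimated correlation) but not by fry (adjusted p = 0.0644). Xcl1 lost its call in 12 of 20 alternatives, those with a mouse left out included, and Klrk1 in 10 of 20.

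**Figure D3:**
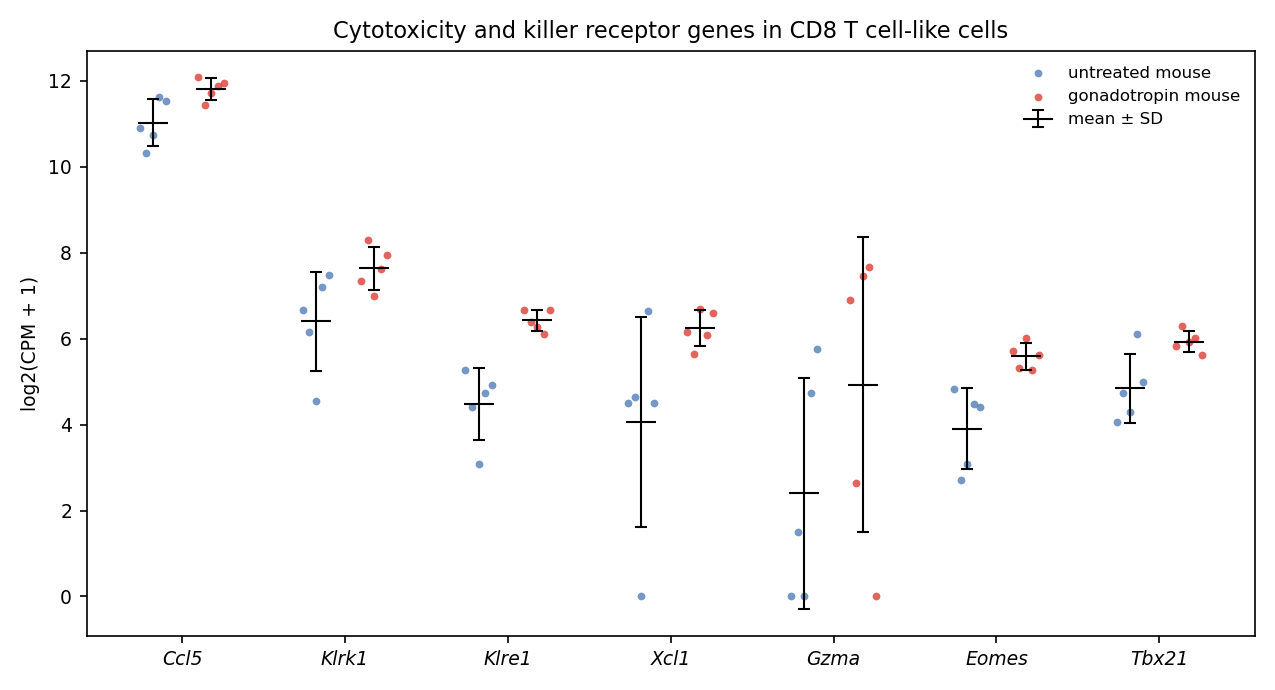
Expression of 7 cytotoxicity and killer receptor genes (horizontal axis) in CD8 T cell-like cells, as log2(CPM + 1) (vertical axis), with 1 point per mouse, untreated in blue and gonadotropin in red, and the mean ± SD of the log values as black bars. Klre1 and Eomes show no overlap between the groups, whereas Gzma spreads widely within both groups and Xcl1 within the untreated mice.

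Tmem163 rose by 1.63 ± 0.33 and Igbp1, a regulatory subunit of protein phosphatases, changed by −0.80 ± 0.20 (edgeR adjusted p at most 0.0343). Genes of recirculation and the naive state were positive in 4 of 12, with Klf2, a transcription factor that keeps T cells recirculating, lower at −0.42 ± 0.09 over all genes and 5 genes lower adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). Ribosomal protein genes were positive in 3 of 25, with 6 lower over all genes and 21 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation), and mitochondrially encoded genes in 2 of 13, with 1 lower over all genes and 2 adjusted over the list alone (adjusted p = 0.499 with an estimated correlation). Cluster 6.3, led by Ccl5, Gzmk and Cxcr6, held 17% ± 9.40 of the CD8 T cell-like cells of gonadotropin and 8.15% ± 4.62 of those of untreated mice (SD, n = 5 each; exact permutation p = 0.103). At the finer clustering resolution, the cluster led by Cd8b1, Cd8a and Dapl1, with Lef1 and Tcf7 among its genes, held 56.9% ± 1.53 and 71.6% ± 7.43 of the CD8 T cell-like cells (SD, n = 5 each; exact permutation p = 0.0079, adjusted p = 0.069). The makeup of the class, and with it that of cluster 4, may differ between the groups. In the other cluster alone, cluster 4 with Lef1 among its leading genes, 33 genes passed, 31 of them shared with the 94 of the whole class. There, Klre1 was at 1.70 ± 0.25, Xcl1 at 1.90 ± 0.31, Eomes at 1.56 ± 0.32 and Klrk1 at 0.99 ± 0.24 (edgeR adjusted p at most 0.0405), and 7 of 7 cytotoxicity genes were positive. Gzma, at 5.19 and 0.66 CPM, Tbx21, at 34.2 and 18.4 CPM, and Tmem163, at 19.7 and 6.61 CPM, were too low to be tested in that cluster. The recirculation list was not called in that cluster, with 6 of 12 positive (limma camera adjusted p = 0.335), though Klf2 was lower at −0.41 ± 0.09. Ccl5, at 0.52 ± 0.22, did not pass in that cluster (edgeR adjusted p = 0.345). Tested directly against NK cell-like cells, the change was more positive in CD8 T cell-like cells for Klre1 (1.72 ± 0.27), Gzma (2.66 ± 0.60), Eomes (1.61 ± 0.35), Klrk1 (1.18 ± 0.26) and Ccl5 (0.70 ± 0.16) (edgeR adjusted p at most 0.0448). The count of 94 was 59 and 52 without gonadotropin mouse 1 or 4 and 45, 43 and 45 without untreated mouse 1, 2 or 5, and 43 with counts thinned to the mouse with the fewest UMIs. The 5 called lists were 3 without gonadotropin mouse 2 and 8 without untreated mouse 2.

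NK cell-like cells, whose mean share was higher, gave 2 calls of 4773 genes (edgeR, n = 5 each), with 364 at an unadjusted p under 0.05. Egr1, an immediate early transcription factor, rose by 1.72 ± 0.31 (SE; edgeR adjusted p = 0.0136), from 45.1 ± 17.4 to 132 ± 69.7 CPM (SD, n = 5 each). The other call was the gene model Gm42418, which rose by 0.60 ± 0.08. The cytotoxicity genes of NK cell-like cells were positive in 4 of 13 (limma camera adjusted p = 0.382), with Ccl5 at 0.05. T cell activation genes were positive in 6 of 10, with Egr1 higher over all genes and 3 adjusted over the list alone (adjusted p = 0.334 with an estimated correlation). Chemokines were positive in 4 of 4, with 0 higher over all genes and 1 adjusted over the list alone (adjusted p = 0.408 with an estimated correlation), and inflammatory genes in 7 of 7, with 0 higher over all genes and 0 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Ribosomal protein genes were positive in 2 of 25, with 0 lower over all genes and 10 adjusted over the list alone (adjusted p = 0.408 with an estimated correlation), and mitochondrially encoded genes in 1 of 12, with 0 lower over all genes and 2 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Cluster 1.2, led by Ccl4, Xcl1, Ccl3, Nr4a3 and Ifng, held 21.2% ± 4.96 of the NK cell-like cells of gonadotropin and 8.16% ± 6.15 of those of untreated mice (SD, n = 5 each; exact permutation p = 0.016, adjusted p = 0.069). In the largest NK cluster alone the chemokine and the inflammatory lists pointed down (limma camera adjusted p = 0.0207 and 0.0237), and Egr1, at 54.5 and 23.6 CPM, was too low there to be tested. The T cell activation list pointed down there as well, with 1 of 4 genes positive, and was not called (limma camera adjusted p = 0.0702). DESeq2 called 27 genes and limma-voom 1, and the edgeR count was 10 without untreated mouse 2 and 1 without gonadotropin mouse 4 or untreated mouse 1 or 4. The 5 called lists were 3 without mouse 3 of either group and 2 without untreated mouse 1.

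One set of genes moved in most types. Fos and Junb were lower and the heat shock genes Hspa1a and Hspa1b higher in B cell-like clusters 0 and 2, CD4 T cell-like and CD8 T cell-like cells (edgeR adjusted p at most 0.0475). In NK cell-like cells Fos was at −0.18 and Junb at −0.52 and neither passed. Egr1, which is on the same stress list, went the other way in NK cell-like cells, at 1.72, and was called. Hspa1a and Hspa1b were too low to be tested there. Together they came to 0.53 ± 0.38 UMIs per cell in gonadotropin and 0.17 ± 0.11 in untreated mice (SD, n = 5 each). The difference between NK cell-like cells and B cell-like cluster 0, at 1.22 ± 0.27 for Fos, did not pass either (edgeR adjusted p = 0.203). Hspa1b, an inducible chaperone on chromosome 17 (34956429 to 34959238, GRCm38.p6), rose by 2.59 ± 0.31 in B cell-like cluster 0, 1.89 ± 0.26 in B cell-like cluster 2, 2.35 ± 0.42 in CD4 T cell-like and 3.65 ± 0.46 in CD8 T cell-like cells (SE). In the last of these it stood at 124 ± 72.7 CPM against 10.9 ± 13.6 CPM (SD, n = 5 each). Hspa1a rose by 1.79 ± 0.34, 1.43 ± 0.31, 2.59 ± 0.45 and 2.82 ± 0.37 in the same order. Not every gonadotropin mouse shared this rise. In B cell-like cluster 0 the lowest gonadotropin mouse held 0.26 UMIs of the 2 genes per cell, against up to 0.353 in untreated mice. In CD4 T cell-like cells the lowest held 0.169, against up to 0.552. In CD8 T cell-like cells gonadotropin mouse 1 held 0.442, against 1.51 to 3.0 in the others and up to 0.357 in untreated mice. Fos changed by −0.81 ± 0.20 in CD4 T cell-like and −1.05 ± 0.18 in CD8 T cell-like cells, and Zfp36, which destabilises cytokine messages, by −0.75 ± 0.18 and −1.19 ± 0.21. In CD8 T cell-like cells the stress list had 5 genes lower and 2 higher, or 7 and 3 adjusted over the list alone, and was not called (limma camera adjusted p = 0.0637). In cluster 4 alone it was called as lower, with 5 of 16 positive (limma camera adjusted p = 2.36e-05). Several of these calls were lost under alternatives or with a mouse left out, that of Fos in CD4 T cell-like cells in 14 of 21, Zfp36 there in 14 of 20 and Hspa1a in B cell-like cluster 2 in 10 of 18, without a change of direction. Hspa1a and Hspa1b are near-identical neighbours, so the split of reads between them is uncertain. Both gene groups belong to a list fixed as a sign of cell dissociation and stress.

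**Figure D4:**
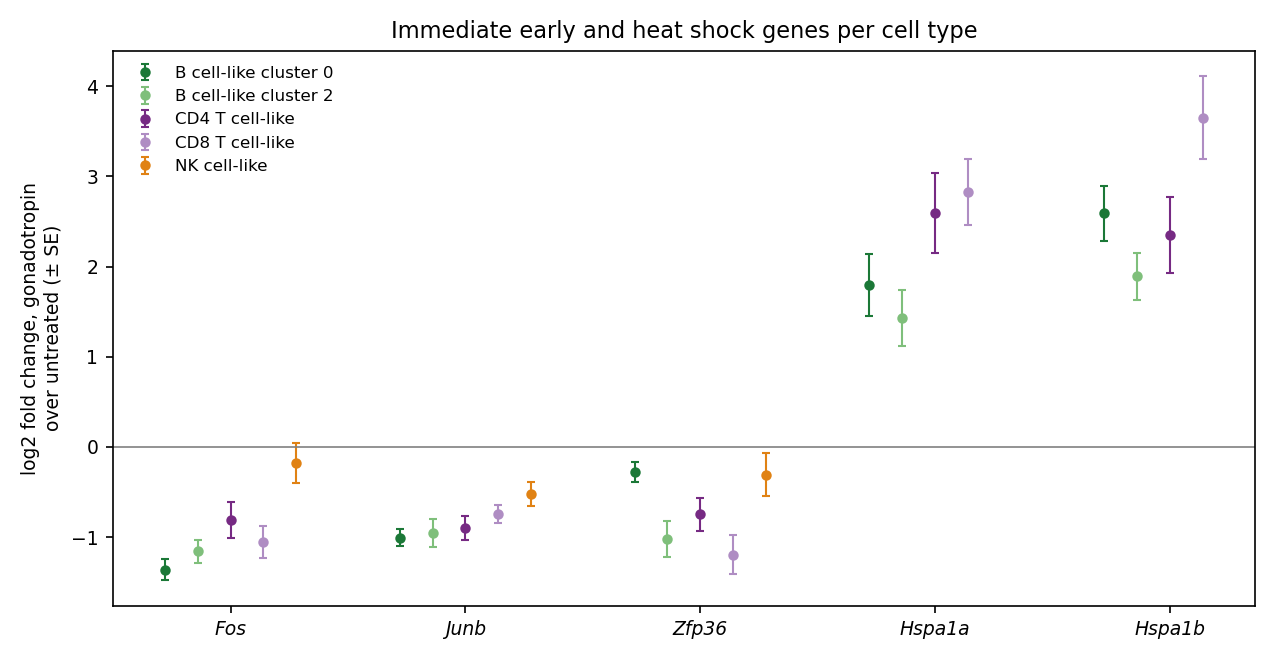
Log2 fold change of gonadotropin over untreated mice (vertical axis, points, with SE as bars) for 5 immediate early and heat shock genes (horizontal axis) in 5 cell types, shown by color, with 4 or 5 mice per group. Hspa1a and Hspa1b were not tested in NK cell-like cells. Hspa1b lies between 1.89 and 3.65 and Fos between −1.36 and −0.18.

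The share of cycling cells was compared after each cell was thinned to 2000 UMIs. Cells with at least 2 UMIs of G2 and M phase genes made up 2.91% ± 1.05 of the CD45+ cells of gonadotropin and 2.78% ± 1.16 of those of untreated mice (SD, n = 5 each; exact permutation p = 0.85). In B cell-like cluster 0 the shares were 1.80% ± 1.99 and 3.46% ± 1.73 (exact permutation p = 0.19), and in CD8 T cell-like cells 4.49% ± 3.38 and 2.12% ± 3.18 (exact permutation p = 0.32; SD, n = 5 each). No tested type passed after adjustment, and neutrophil-like cells, which do not divide, gave 9 of 75 gonadotropin and 2 of 36 untreated cells by the same count. ILC1-like cells, with Mki67 and Top2a among their genes, gave 0 of 27 gonadotropin and 3 of 30 untreated cells. The count thus takes in cells that do not divide, and it cannot tell dividing cells from background in the tested types. Thinning left out 67 and 36 shallower cells, and without it the shares were 17.9% and 16.2%.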

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

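The tests of explanations in this part, the comparison of changes between cell types in the paragraphs on differences, and the look at hashtag doublets were all chosen after the results were seen.

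In the leukocytes of gonadotropin mice Hspa1a and Hspa1b were higher, and Fos and Junb lower, in B cell-like clusters 0 and 2, CD4 T cell-like and CD8 T cell-like cells. The heat shock rise was not seen in every gonadotropin mouse, as given above. A difference in depth is left open. Every mouse of a type was thinned to the same number of UMIs, and all 16 of the 16 changes kept their sign and at least 0.5 of their size. Random thinning of summed counts leaves the expected CPM unchanged, though, so this cannot decide whether depth played a part. For the heat shock genes, the ratio of UMIs per cell in CD8 T cell-like over NK cell-like cells was at least 1.58 in each of the 5 gonadotropin mice. The depth of the 2 types gives 1.37. That is no upper limit for free RNA, since Hbb-bs, which free RNA may carry, ran from 0.3 to 1.80. In mice 1 to 5 the heat shock ratios were 8.85, 8.24, 3.0, 1.58 and 4.42, against 1.80, 1.39, 0.3, 0.63 and 1.06 for Hbb-bs. Being higher in each mouse, the heat shock ratios argue against free RNA as the whole cause. They rest on few UMIs, with 0.05 and 0.217 per NK cell-like cell in gonadotropin mice 1 and 2, which held 100 and 23 such cells. NK cell-like cells held 0.53 ± 0.38 of the heat shock UMIs per cell in gonadotropin and 0.168 ± 0.112 in untreated mice (SD, n = 5 each). Free RNA of a pool would add alike to all its mice. The gonadotropin mice ran from 0.05 in mouse 1 to 0.952 in mouse 4, which argues against free RNA as the main source there too. A small part is left open. Free RNA is argued against for Fos too, whose UMIs per cell changed by −0.193 ± 0.197 (SE) in NK cell-like cells and by −1.17 ± 0.241 in B cell-like cluster 0. The difference was 0.981 ± 0.311. That SE takes the 2 types as independent though they share their mice, so it may be too small. Unlike the other untreated mice, mouse 4 held more Fos in NK cell-like cells (1.55) than in B cell-like cluster 0 (1.08). The same contrast in edgeR, with the mouse as a term, did not pass (adjusted p = 0.203). Handling or library of the 2 pools and an effect of the hormone cannot be told apart, as there was 1 library per group.

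Hemoglobin transcripts reached B cell-like cluster 0 of the gonadotropin mice, and the kept erythrocyte-like cells were all of gonadotropin mice, though 2 hashtag doublets of the untreated pool were placed with them. Free RNA from lysed erythrocytes may be the source in B cells, because gonadotropin mouse 2, which had no kept erythrocyte-like cell, held 34.6 CPM of Hbb-bs in its B cells against 19.5 to 34.5 in the other gonadotropin mice and at most 4.52 in the untreated mice. B cells caught together with an erythrocyte are argued against, since the highest count in 1 B cell was 4 Hbb-bs UMIs against a median of 5923 in erythrocyte-like cells. Whether the erythrocyte-like cells themselves reflect blood left in the tissue, handling of the pool or bleeding at follicle rupture cannot be told apart with 1 library per group, and a sort for CD45 would be expected to remove them.

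Barcodes carrying more than 1 hashtag held a macrophage-rich set in the gonadotropin pool, with 117 of them placed in the macrophage cluster 5.4 against 5 in the untreated pool, and 160 with at least 100 UMIs of macrophage markers against 25. A high share of hashtag doublets was not particular to this cluster or pool. In the gonadotropin and untreated pools it was 51.0% and 49.1% in macrophage cluster 5.2, 54.4% and 45.0% in cDC2-like cells and 53.8% and 41.9% in B cell-like cluster 2. A macrophage caught with a random second cell is argued against, as B cell markers were found in 11.9% of the 160 (7.30 to 17.9; Clopper-Pearson) while 44.3% of all kept gonadotropin cells carry them. Pairs of macrophages in 1 droplet cannot be told apart from other sources, because the UMIs of these barcodes over those of single-hashtag cells came to 1.04 (0.825 to 1.3, from resampling) in cluster 5.4 and 1.77 (1.53 to 2.31) by the marker limit, with 1.5 for doublets of B cell-like cluster 0. The marker limit is not confined to 1 cluster. Within cluster 5.2 of the gonadotropin pool the medians were 14025.5 UMIs in hashtag doublets and 12846.5 in single-hashtag cells. Staining or handling of the pool, such as macrophages that bind several hashtags, stays open as well, with 1 library per group. Hashtag doublets made up 82.4% of the gonadotropin barcodes placed in cluster 5.4, so the macrophage share given for these mice may be too low.

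Some mice stood far from the others of their group, in 12 of 223 groups of values tested, where chance gives about 1 in 20, or 11.2. Among shares, gonadotropin mouse 2 had 6.08% NK cell-like cells against 14.6% to 17.8% in the others and 2.91% cDC2-like cells against 0.355% to 1.03%. In all CD45+ cells untreated mouse 4 stood at 89.2 CPM of Ctla4 (others 45.9 to 54.7) and 347 CPM of Agbl1 (258 to 279), and gonadotropin mouse 1 at 11.5 CPM of Nid1 (23.4 to 28.0). In B cell-like cluster 0 gonadotropin mouse 2 had 448 CPM of Stat4 (305 to 334). In CD4 T cell-like cells gonadotropin mouse 3 stood at 449 CPM of Lgals1 (216 to 276), 56.9 CPM of Pde4d (87.7 to 94.1) and 326 CPM of Gas5 (423 to 433), untreated mouse 1 at 759 CPM of Junb (515 to 578) and untreated mouse 4 at 436 CPM of Gas5 (573 to 622). In CD8 T cell-like cells gonadotropin mouse 1 had 70.6 CPM of Tmem163 (36.2 to 42.7).

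The genes given here are all those whose change after gonadotropin differed between cell types at an adjusted p of 0.05 in edgeR. Most of them lie outside the naming rule and were chosen after their values were seen. When the mice were divided in other ways, chance was excluded only for CD8 T cell-like cells against NK cell-like cells and against B cell-like cluster 0, as given at the end. CD8 T cell-like cells differed from NK cell-like cells in 14 genes, with log2 differences of 1.69 for Ikzf2, 1.82 for Tmem163, 2.51 for Zeb2, 1.24 for B4galt5, 1.72 for Klre1, 1.18 for Klrk1, 1.67 for Klra7, 1.62 for Lrrk1, 0.97 for Itgb1, 1.61 for Eomes, 0.70 for Ccl5, 0.88 for Ctla2a, 2.66 for Gzma and 1.39 for Dnah8. They differed from B cell-like cluster 0 in 13, at 2.53 for Zeb2, 1.24 for B4galt5, −3.65 for Atp10a, 1.65 for Lrrk1, 1.15 for Itgb1, 3.23 for Tbx21, −0.78 for Ccr7, 1.25 for Lgals1, 0.95 for Prr13, 1.04 for Ahnak, 1.23 for Mirt1, −0.94 for Fgf13 and −4.09 for Zc3h12b. CD4 T cell-like cells differed from that cluster in 7, at 1.43 for Cd44, 2.64 for S100a4, 2.29 for S100a6, 3.16 for Plac8, 1.56 for Lgals1, 1.38 for Ahnak and −0.96 for Fgf13, and NK cell-like cells in 2, at 1.87 for Nr4a1 and 2.0 for Egr1.

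Compared with CD4 T cell-like cells, NK cell-like cells differed in 4 genes, at −2.04 for S100a6, 1.01 for Dennd4a, −2.37 for Ccr2 and −1.24 for Lgals1, CD8 T cell-like cells in 2, at −2.97 for Plac8 and 2.23 for Itm2a, and B cell-like cluster 2 in 1, at −1.85 for Ctla4. The pairs B cell-like clusters 0 and 2, cluster 2 and NK cell-like, and cluster 2 and CD8 T cell-like gave 0 calls in edgeR, the only tool run on differences, with 443, 313 and 437 genes at an unadjusted p under 0.05.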

How the results depend on the processing

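The tests with hashtag doublets counted by a tag or by the deposited mouse column, cells near hashtag doublets left out, erythrocyte-like cells or stress genes left out, the largest cluster alone, thinned counts per type, and lists with a mouse left out or blocked were chosen after the results were seen, and the rest were fixed before. Each of those fixed before was run, though with at least 50 cells per mouse too few mice were left in B cell-like cluster 2 and NK cell-like cells. Where no reason is given, the cause was not tested.

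Of the named genes 1821 of 2242 values under other settings kept direction and side of the threshold, 409 lost the call and 12 reversed, and with a mouse left out 1615 of 2251 kept both. With erythrocyte-like cells left out 114 of 114 did. Over its alternatives, those with a mouse left out included, Hspa1b ran from 2.38 to 2.99 in B cell-like cluster 0 and from 3.32 to 4.27 in CD8 T cell-like cells, Fos from −1.45 to −1.28 in B cell-like cluster 0 and Klre1 from 1.5 to 1.90 in CD8 T cell-like cells, none losing its call. Others lost theirs often, such as Fos in CD4 T cell-like cells (14 of 21, from −1.01 to −0.63), Zfp36 there (14 of 20), Hspa1a in B cell-like cluster 2 (10 of 18, from 1.06 to 1.92) and, in CD8 T cell-like cells, Dusp1 (15 of 19), Xcl1 (12 of 20, from 1.15 to 1.92), Klrk1 (10 of 20) and Tbx21 (9 of 19). With equal cell numbers per type, all cells reversed for Il1r2 (−0.74), Klrk1 (−0.073), Mgst1 (−0.15), C5ar1 (−0.31), Nkg7 (−0.028), Agbl1 (0.15), Prf1 (−0.0049), Lrp1 (−0.073) and mt-Co3 (0.017). That setting is by construction without the shift in cell mix, but it also holds fewer cells. Lgals1 reversed in the largest CD4 cluster (−0.29), and S100a4 in B cell-like cluster 2 without the UMI extremes (−0.64) and without cells near doublets (−0.34).

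Shares kept direction and side in 166 of 189 values. At another clustering resolution, with fewer groups to adjust for, B cell-like cluster 2 (−10.1 percentage points) and all B cells (−12.5) passed. With hashtag doublets by first tag B cell-like cluster 2 (−12.4), all B cells (−16.0), macrophage-like (7.75) and neutrophil-like cells (1.44) passed, and ILC2-like (−0.113) and mast cell-like cells (−0.0392) reversed. None of these passed with the doublets given to their other tag (B cell-like cluster 2 −11.4, all B cells −15.8, macrophage-like 7.47, neutrophil-like 1.42), where cDC2-like (0.0846) and ILC2-like cells (−0.0253) reversed, or by the deposited mouse column (−11.7, −15.4, 7.14 and 1.32), where ILC2-like (−0.127) and mast cell-like cells (−0.00542) did. Gene counts with doublets were taken by the first tag only. Reversed as well, none past the threshold, were ILC1-like (0.0161) and B cell-like cluster 10 (0.252) on the log2 scale, cluster 6.1 (0.0315), regulatory T cell-like (0.0756) and ILC1-like cells (0.0384) without the UMI extremes, mast cell-like cells (−0.000893) without the most changed type, cluster 6.1 (0.0946) and B cell-like cluster 10 (0.0665) at the other resolution, cDC2-like cells (0.261) without cells near doublets, and unthinned cycling cells in B cell-like cluster 2 (1.48) and NK cell-like cells (7.06).

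With 1 mouse left out the differences ran, in percentage points, from −0.215 to 0.0606 for B cell-like cluster 10, −2.91 to 0.619 for CD4 T cell-like, −0.268 to 0.232 for ILC1-like, −0.657 to 0.00828 for cDC2-like, −0.0598 to 0.163 for mast cell-like, −0.0684 to 0.218 for plasmacytoid dendritic cell-like cells and −0.489 to 0.285 for cluster 6.1, and for cycling cells from −1.17 to 0.664 in B cell-like cluster 2, −0.994 to 0.453 in NK cell-like and −0.274 to 0.476 in all cells.

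Counts of changed genes moved by more than 1.5 times in 33 of 80 cases. All cells gave 49 with an equal mix (41 shared) and 2160 with doublets by first tag (883 shared). B cell-like cluster 0 gave 244 without the count filter (101 shared), 44 with the mouse number as block (44) and 48 with thinned counts (40). CD4 T cell-like cells gave 116 without the filter (45), 28 with the block (27), 21 with at least 50 cells (13), 27 without the UMI extremes (26), 22 thinned (18) and 106 with doublets (45). B cell-like cluster 2 gave 89 without the filter (26), 41 with the block (23), 7 without the UMI extremes (5), 1 without cells near doublets (1) and 68 with doublets (21). NK cell-like cells gave 27 in DESeq2 (1), 41 without the filter (2), 11 with the block (2), 4 with doublets (2), and 1 each in limma-voom, without stress genes, without the UMI extremes and thinned. CD8 T cell-like cells gave 158 without the filter (86), 54 with the block (52), 43 thinned (40) and 33 in the largest cluster (31). With 1 mouse left out the counts ran from 682 to 1063 in all cells (lowest without gonadotropin mouse 4), 37 to 242 in B cell-like cluster 0, 7 to 76 in CD4 T cell-like, 8 to 29 in B cell-like cluster 2, 1 to 10 in NK cell-like and 43 to 119 in CD8 T cell-like cells. The block is no pairing, as mice of the same number were not the most alike in any of 5 cases.

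Called lists rest on the preset correlation. With an estimated correlation the counts were 0 in all cells, B cell-like clusters 0 and 2, CD4 T cell-like and NK cell-like cells and 1 in CD8 T cell-like cells. Fry gave 7 in all cells, 2 in B cell-like cluster 0, 2 in CD4 T cell-like and 0 in B cell-like cluster 2, NK cell-like and CD8 T cell-like cells, and library size in place of TMM gave 3 in CD8 T cell-like cells. With 1 mouse left out the counts ran from 11 to 16 in all cells, 5 to 8 in B cell-like cluster 0, 5 to 7 in CD4 T cell-like, 3 to 5 in B cell-like cluster 2, 2 to 5 in NK cell-like and 3 to 8 in CD8 T cell-like cells. The stress list in B cell-like cluster 0 had adjusted p from 0.000152 to 0.952 and reversed without gonadotropin mouse 1. Small changes may be missed, since simulated changes of 1.5-fold, at the depths and replicate numbers of these data, were recovered in 28.4% to 59.7% of genes.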

Other observations

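Macrophages, monocytes and neutrophils, the cells that clear and remodel ovarian tissue, were too few per mouse for the main comparison and were tested with fewer cells per mouse. All tests in this part were chosen after the results were seen. In macrophage-like cells (at least 10 cells per mouse) edgeR called 0 of 2558 genes, with 147 at an unadjusted p under 0.05, 11 in DESeq2 and 0 in limma-voom. Complement genes (camera adjusted p = 0.0199; 0.399 with an estimated correlation) and matrix remodelling genes (0.00424; 0.268) pointed down in gonadotropin mice. The makeup of the type is part of this comparison, as cluster 5.5, with Saa3, Prg4, Thbs1 and C4b among its genes, held 3.96% ± 2.84 of it in gonadotropin and 14.8% ± 10.9 in untreated mice (SD, n = 5 each; exact permutation p = 0.016, adjusted p = 0.069). In neutrophil-like cells (at least 5 cells) edgeR called 0 of 799 genes, with 65 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom, and lipid uptake genes pointed down (camera adjusted p = 0.00137; 0.23 with an estimated correlation).

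Non-classical monocyte-like cells (at least 5 cells, 5 gonadotropin and 3 untreated mice) gave 4 genes of 2017, all lower, with mt-Nd4 at −0.80, Fth1 at −0.80, Ptger4 at −2.30 and Dusp2 at −1.49, while 183 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 2. Their inflammatory and NF-kB list pointed down by both correlations (adjusted p = 1.05e-05 and 0.0403), and the prostaglandin list by the preset one (0.000319; 0.0659). Classical monocyte-like cells (at least 3 cells) gave 0 of 1404 genes in edgeR, with 153 at an unadjusted p under 0.05, 3 in DESeq2 and 1 in limma-voom. The stress list pointed down in all 4 types, at an adjusted p of 6.4e-10 in macrophage-like, 0.00411 in neutrophil-like, 0.0115 in non-classical and 3.02e-05 in classical monocyte-like cells, and at 0.184 to 0.264 with an estimated correlation.

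The mice were also divided in other ways, into groups of the same sizes. The real grouping is counted among the splits, so 1 with as many means that no other split reached its count. For changed genes chance can be excluded in all CD45+ cells (1027 genes, 23 in the highest other of 100 splits, 1 with as many), CD4 T cell-like (48 against 20; 1 with as many), B cell-like cluster 2 (26 against 7; 1) and CD8 T cell-like cells (94 against 22; 1). In NK cell-like cells (2 against 6; 4 with as many) the share lies just under the limit of 0.05 of the splits, which was not adjusted over the tests. With 2 genes called and more in another split, chance is left open there. In B cell-like cluster 0 (104 genes; 2 with as many) the share lies under the limit, but a split that exchanged gonadotropin mouse 2 and untreated mouse 4 called 249 genes. That points to a structure of the samples, and chance is left open for this count too. Leaving out gonadotropin mouse 2 gave 242 genes and leaving out untreated mouse 4 gave 227 in B cell-like cluster 0, while the same exchange called 23 genes in all CD45+ cells. For non-classical monocyte-like cells the shares for genes (4 against 2; 1 of 56 splits) and lists (6 against 8; 2) lie under that limit. Another split called more lists, though, DESeq2 called 0 genes, and the type was chosen after the results were seen. Chance is therefore left open there as well. For genes in macrophage-like, neutrophil-like and classical monocyte-like cells the real count was 0, so all 100 splits gave as many by construction and the splits say nothing about chance.

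For called lists chance cannot be excluded in all CD45+ cells (11 against 21; 44 of 100 splits with as many), B cell-like cluster 0 (8 against 10; 8), CD4 T cell-like (6 against 7; 14), B cell-like cluster 2 (3 against 9; 51), NK cell-like (5 against 6; 10), CD8 T cell-like (5 against 8; 19), macrophage-like (4 against 9; 47), neutrophil-like (4 against 7; 19) and classical monocyte-like cells (1 against 5; 61). For genes whose change differed between types it can be excluded for CD8 T cell-like against NK cell-like cells (14 against 5; 1 of 60 splits) and against B cell-like cluster 0 (13 against 5; 1). For B cell-like cluster 0 against CD4 T cell-like cells (7 against 7; 2) the share lies under the limit, but another split called as many genes, so chance is left open. Chance cannot be excluded for B cell-like cluster 0 against NK cell-like (2 against 5; 12) or for CD4 T cell-like against NK cell-like (4 against 5; 4), CD8 T cell-like (2 against 5; 16) and B cell-like cluster 2 (1 against 6; 25).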
